A study of Homo sapiens with 6 samples.

How the data were processed

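Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA. The cells were labelled DAMI, a human leukaemia line, and the identity of the line was not checked here. Per the labels' protocols, 50000 cells were tagmented with 2 µl of Tn5 for 45 min at 37 °C. The labels give 6 samples in 2 groups: 3 infected with a control lentivirus and 3 infected with a lentivirus that silences HMGA1 by short hairpin RNA (shHMGA1). The series text also mentions a SET-2 cell line, which was not analysed here.

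The deposited data analysed here were 2 peak lists in narrowPeak format, 1 per group. Each list was given its group from its own name (Con or shHMGA1), since the lists have no header. Per the submitters' processing notes, the peaks were called with Genrich on hg19. The Genrich version and settings, the aligner, the read filters and the way the 3 samples of a group were combined are not given in the sources used here. It is also not given whether libraries of another cell line entered the lists. The deposited files hold no values per sample, so n is 1 list per group. Differences between the lists therefore have no replicate check, and no p-value is given for any of them.

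The authors' lists hold 4 kinds of value per peak. The positions and summit offsets, as deposited, are whole bases on hg19. The deposited summit value is a −log10 p written by the peak caller and not adjusted for multiple testing; the q-value column is −1 in every row. The deposited signal column is the area under the significance curve of the peak, which grows with width; its smallest value is just above 200.0 in both lists. The deposited score equals 1000 times that area divided by the width, rounded to the nearest whole number and capped at 1000, exactly in 127153 of 127153 control rows and 112608 of 112610 shHMGA1 rows. These values are the authors' own and depend on read depth and on how samples were combined. They were used to rank peaks within a list and, in some alternatives, to filter both lists at a joined threshold. List medians were set side by side, but the height of a peak was never compared between lists. Read depth is unknown, because the deposited files hold no read counts.

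Peaks were compared by overlap with bedtools 2.31.1. A peak was called shared where at least 1 bp overlapped a peak of the other list, and otherwise control-only or shHMGA1-only. The overlap that spacing alone gives was estimated from 100 circular shifts of the other list within each chromosome. Each list was divided into 10 equal parts (deciles) by summit −log10 p. Intervals on shares of peaks are 95% binomial intervals, by Wilson's method for shares of all peaks and the exact Clopper-Pearson method for shares of unshared peaks. A share of 0 is given with the limit set by 3 counts. Intervals and limits cover counting error only, treat neighbouring peaks as independent and do not include variation between cultures. For peaks that overlapped exactly 1 peak in the other list and the reverse, the log2 ratio of the widths was taken.

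Peaks were assigned by summit to hg19 chromosome bands, taken from the band table shipped with the R package circlize, whose chromosome ends matched the hg19 lengths. Band, segment and block results were restricted to chromosomes 1 to 22 and X. Dense segments were runs of at least 5 consecutive 1-Mb windows with at least 4 times the median number of peaks of occupied windows in both lists. Blocks were runs of at least 3 neighbouring bands, each with at least 50 control peaks and each with a ratio of peak numbers over 15% below, or over 15% above, that of the whole lists. The rules for segments, blocks, extreme bands (at least 100 control peaks, the 5 lowest and 5 highest ratios) and the bands of known genes were set after the data were examined. The block rule followed an exploratory look with other ratio cut-offs, which gave more blocks than the rule reported here. The overlap comparisons, the alternatives listed as planned and the rule for named sites (the 10 most significant unshared peaks of each list on chromosomes 1 to 22 and X) were set before the data were examined.

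For the comparison of neighbouring bands, the share given by peak strength was computed from the unshared rate of 50 classes of summit significance in each list, over bands with at least 20 unshared peaks, and set against 10000 shuffles of the bands. The overlap, pairing and regional counts were tested on simulated lists made from the 127153 control peaks, in which 0% of peaks received a wrong shared state and 6874 of 6874 planted peaks were recovered. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were a reciprocal overlap of 50%, a distance of 500 bp, a stricter significance threshold, equal numbers of peaks from each list, chromosomes 1 to 22 and X, merging of peaks within 150 bp, and, added later, filtering 1 list only and leaving out the dense segments. The alternatives on blocks, on densities of the segments and on the control-only share were also added after the data were examined. The promoter, gene list, base composition and motif comparisons planned before the data were examined were not run, because no hg19 gene annotation or sequence was used here. Peaks were for that reason not assigned to genes, exons, introns or promoters. Gene names appear only with the chromosome band that is known to hold them.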

Results

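The cells were labelled DAMI, a human leukaemia line, and the title of the series places the work in the progression of myeloproliferative neoplasms. HMGA1 is an architectural chromatin protein that binds AT-rich DNA, and the design asks how its silencing alters accessible chromatin. Accessible regions were given as 1 peak list for control cells and 1 for shHMGA1 cells, each from a group of 3 samples. The control list held 127153 peaks covering 90.4 Mb, and the shHMGA1 list held 112610 peaks covering 82.1 Mb. Read depth is unknown, and with 1 list per group no difference below has a replicate check.

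The shHMGA1 list was shorter than the control list. It held 14543 fewer peaks (11.4% fewer), a ratio of 0.886, and covered 9.13% fewer bases. The number of peaks was lower on each of chromosomes 1 to 22 and X, with ratios from 0.811 on chromosome X and 0.819 on chromosome 11 to 0.954 on chromosome 17. Peak shapes were close in the lists. Median width was 525 bp (quartiles 325 and 859) in control and 539 bp (quartiles 334 and 880) in shHMGA1. The median summit −log10 p, as called by the authors, was 5.25 and 5.22. Among 83581 regions with exactly 1 peak in each list, the shHMGA1 peak was the wider in 44.8% (95% Wilson interval 44.5 to 45.1), with a median log2 width ratio of -0.03.

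Most accessible regions were present under both conditions. Of the control peaks, 95518 (75.1%, 95% Wilson interval 74.9 to 75.4) overlapped an shHMGA1 peak. Of the shHMGA1 peaks, 95928 (85.2%, interval 85.0 to 85.4) overlapped a control peak. Circular shifts gave mean overlaps of 6.47% (range 4.33 to 12.7) and 7.46% (range 4.87 to 14.8). The 2 lists had 66.7 Mb in common, 63.0% of the 106 Mb in either. The unshared peaks were 31635 control-only and 16682 shHMGA1-only, so 65.5% of all unshared peaks were control-only (exact interval 65.0 to 65.9). These counts moved by over 1.5 times with the rules of calling and overlap. A reciprocal overlap of 50% gave 47878 control-only and 33335 shHMGA1-only peaks, and filtering only the counted list at the joined median left 2567 and 833. With equal numbers of the most significant peaks from each list, 50.8% of the unshared peaks were control-only. Equal list lengths largely fix such a near-even split.

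The unshared peaks were the weak ones of each list. In the weakest decile of control peaks 38.8% were shared, in the fifth decile 73.8%, in the eighth 99.2%, and in the most significant decile 100%. No peak of that decile was missing from the shHMGA1 list (0 of 12715, which allows up to 0.0236%). In the shHMGA1 list, 56.3% of the weakest decile and 100% of the most significant decile were shared (0 of 11261 unshared, which allows up to 0.0266%). Of the control-only peaks, 92.1% lay below the median significance of their list, and of the shHMGA1-only peaks 94.8%. Control-only peaks had a median width of 353 bp against 610 bp for shared control peaks, and the shHMGA1-only peaks had 360 bp against 585 bp. In the top 3 deciles, 104 of 38145 control peaks (0.273%) and 47 of 33783 shHMGA1 peaks (0.139%) were unshared.

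**Figure D1:**
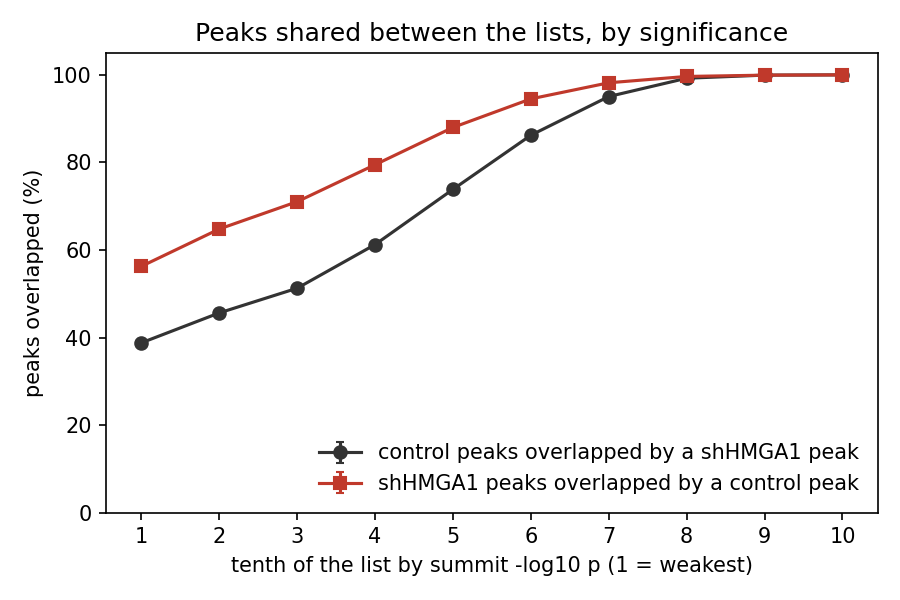
Share of peaks (y axis, %) of each list that overlap a peak of the other list, by decile of the list in order of summit −log10 p (x axis, 1 is the weakest); points are shares and bars, mostly hidden by the points, are 95% Wilson intervals. Sharing rises from 38.8% (control) and 56.3% (shHMGA1) in the weakest decile to 100% in the most significant decile.

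The most significant control-only site lay on chromosome 8 from 74015501 to 74015873 (hg19, band 8q21.11). It was 373 bp wide with a summit −log10 p of 8.88, and the nearest shHMGA1 peak was 8379 bp away. The next were at chromosome 11 from 102680634 to 102681413 (11q22.2) and from 120906624 to 120907140 (11q23.3), with shHMGA1 peaks only 359 and 545 bp away. The other named control-only sites began at 62928719 on chromosome X, 33441865 on chromosome 18, 170107918 and 115289355 on chromosome 6, and 208288403, 152109705 and 200260151 on chromosome 2. Their summit values ran from 8.26 down to 7.94. The first of these 10 sites ranked 20500 among all control peaks by significance.

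The most significant shHMGA1-only site was on chromosome 3 from 1030153 to 1030833 (hg19, band 3p26.3). It was 681 bp wide with a summit −log10 p of 10.7, ranked 11347 in its list, and the nearest control peak was 85859 bp away. Next came chromosome 5 from 121693930 to 121694596 (5q23.2; 8.76), chromosome 4 from 84241540 to 84242324 (4q21.23; 8.72) and chromosome 7 from 90570856 to 90571720 (7q21.13; 8.59). The remaining named sites began at 95825164 on chromosome 5, 28127322 on chromosome 4, 64940648 on chromosome 3, 66209930 on chromosome 8, and 61026161 and 39101235 on chromosome 10. Their summit values ran from 8.37 down to 8.01, and the last lay 197 bp from a control peak. Genes at these sites were not annotated here.

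Accessible peaks were packed into 2 chromosome segments under both conditions. On chromosome 4 from 154000001 to 189000000 (hg19, 4q), the control list held 12810 peaks, or 366 per Mb, and the shHMGA1 list 11765, or 336 per Mb. That is a ratio of 0.918 for the segment. The last 10 Mb of 4q, partly within it, held 2843 control and 2186 shHMGA1 peaks, a lower ratio of 0.769. On chromosome 9 from 2000001 to 21000000 (9p) the lists held 7930 and 7540 peaks, 417 and 397 per Mb. The chromosome 9 segment includes band 9p24.1, which holds JAK2, the kinase gene mutated in most myeloproliferative neoplasms. Against the rest of chromosomes 1 to 22 and X, control peaks were 10.3 times as dense in the 4q segment and 11.7 times as dense in the 9p segment. In shHMGA1 cells the values were 10.8 and 12.7 times. Together the segments made up 1.78% of these chromosomes and 16.4% of control peaks (Wilson interval 16.2 to 16.6). With equal numbers of the most significant peaks from each list, control density fell to 5.10 times the rest on 4q and 9.42 times on 9p.

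The 9p segment ended at an interval without a single peak. No peak of either list lay on chromosome 9 between 20984319 and 24756408 (9p21.3), a length of 3.77 Mb. The band 9p21.3 holds CDKN2A, the cyclin-dependent kinase inhibitor gene. The 1 Mb before the interval held 374 control and 307 shHMGA1 peaks, and the 1 Mb after it 463 and 465. It was the longest of 32 peak-free intervals of at least 1 Mb outside centromeric, variable and stalk bands; the next longest measured 1.85 Mb.

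**Figure D2:**
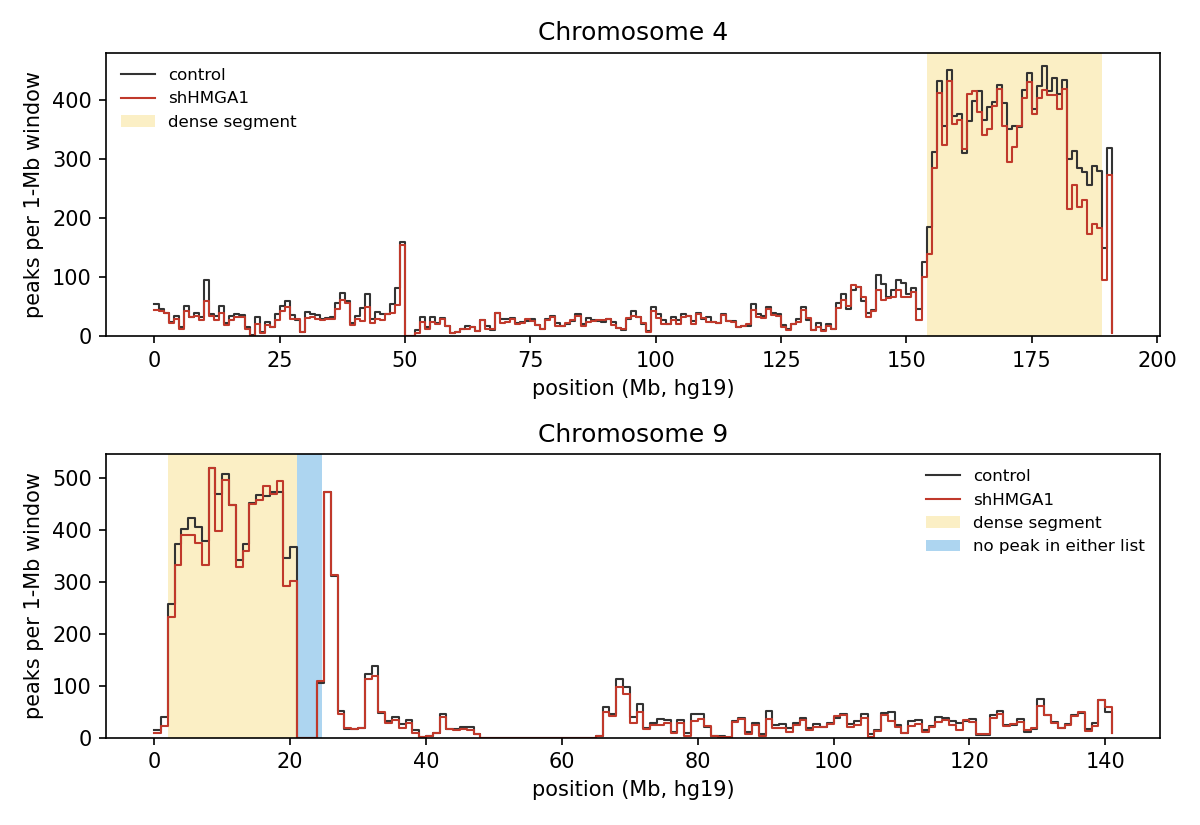
Peaks per 1-Mb window (y axis) along chromosomes 4 and 9 (x axis, Mb on hg19) for the control (black) and shHMGA1 (red) lists, with the dense segments and the longest peak-free interval shaded. Both lists rise in the dense segments, to averages of 366 and 336 peaks per Mb on 4q and 417 and 397 per Mb on 9p. Both are at 0 across 3.77 Mb of 9p21.3.

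The difference between control and shHMGA1 lists was not even along the chromosomes. Among 436 bands with at least 100 control peaks, the ratio of shHMGA1 to control peaks had a median of 0.883, and 5th and 95th percentiles of 0.717 and 1.03. It was below 1 in 386 bands and above 1 in 43. The lowest ratios were those of 11q24.1 (158 control and 95 shHMGA1 peaks, 0.601), 2p25.3 (0.605), 11q24.2 (0.637), 11q23.2 (0.638) and 11q25 (0.642). The highest were those of 1p34.3 (310 control and 421 shHMGA1 peaks, 1.36), 21q22.3 (507 and 633, 1.25), 1p34.2 (1.23), 6q24.1 (1.14) and 1p36.12 (1.12). These 10 bands were picked for their ratios.

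Neighbouring bands formed 4 blocks, chosen by their ratios. On chromosome 11 from 121200001 to the end at 135006516 (11q24.1 to 11q25, 4 bands) the count was 1180 in control and 765 in shHMGA1 cells, a ratio of 0.648. Covered length there was 884 kb and 580 kb, with mean widths of 749 and 759 bp. Of the unshared peaks 523 were control-only and 88 shHMGA1-only, a control-only share of 85.6% (exact interval 82.6 to 88.3). The regions with 1 peak in each list were also narrower in shHMGA1, with a median log2 width ratio of -0.15 over 563 pairs. With equal numbers of the most significant peaks from each list, the ratio of the block was 0.874 (interval 0.757 to 1.01). At that setting 83 peaks were control-only and 24 shHMGA1-only. This block contains 11q24.3, the band of FLI1, an ETS transcription factor of megakaryocytes, where 469 control and 317 shHMGA1 peaks were called. The fall was uneven within this band. A full 1-Mb window of it held 255 control and 203 shHMGA1 peaks, and the next held 100 and 47. The position of FLI1 in the band was not annotated here, so the band counts are not values of the gene.

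The opposite was seen on chromosome 1 from 32400001 to 46800000 (1p35.1 to 1p34.1, 4 bands), with 977 control and 1192 shHMGA1 peaks, a ratio of 1.22. Covered length was 845 kb in control and 1068 kb in shHMGA1, with mean widths of 865 and 896 bp. Here 154 unshared peaks were control-only and 368 shHMGA1-only, a control-only share of 29.5% (exact interval 25.6 to 33.6), and the median log2 width ratio of 703 pairs was 0.06. Above the joined median significance the ratio of the block was 1.01, with 52 control-only and 65 shHMGA1-only peaks, so the numbers were nearly equal there. The whole-list ratio at that threshold was 0.873, so the block still lay above it. With equal numbers of the most significant peaks from each list, the ratio of the block was 1.12 (interval 0.984 to 1.27), with 28 control-only and 86 shHMGA1-only peaks. The block contains 1p34.3, the band of CSF3R, the granulocyte colony-stimulating factor receptor gene. Smaller blocks were 10q26.13 to 10q26.3 (280 control and 202 shHMGA1 peaks, 0.721) and 5q13.2 to 5q14.1 (191 and 215, 1.13). Their unshared peaks were 89 control-only against 11 shHMGA1-only in the 10q block (control-only share 89.0%, exact interval 81.2 to 94.4) and 24 against 51 in the 5q block (32.0%, 21.7 to 43.8). Since the blocks were chosen by their ratios, such shares lie away from the whole-list value in part by that choice.

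**Figure D3:**
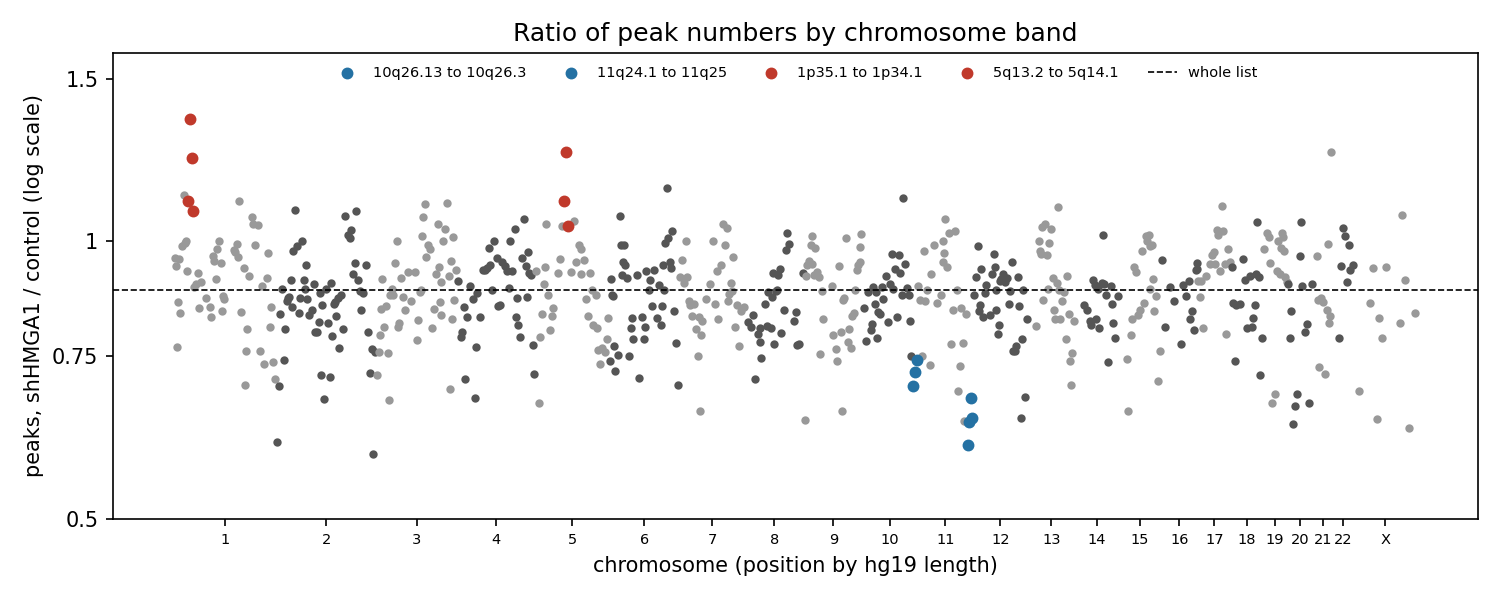
Ratio of shHMGA1 to control peak numbers (y axis, log scale) for chromosome bands with at least 50 control peaks, placed along chromosomes 1 to 22 and X (x axis); the dashed line is the whole-list ratio of 0.886, and coloured points are bands in blocks below (blue) or above (red) it. The 11q block lies at 0.648 and the 1p block at 1.22.

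The bands of 17 known genes, named after their values were seen, had ratios from 0.676 for FLI1 to 1.36 for CSF3R. At the chromosome bands of the targeted gene and of the blood cell regulator GATA2, peak numbers were nearly equal. In 6p21.31, the band of HMGA1, there were 113 control and 112 shHMGA1 peaks, of which 21 and 19 were unshared. In 3q21.3, the band of GATA2, there were 95 and 94 peaks, of which 12 and 13 were unshared. The exact intervals of the control-only share, 36.1 to 68.5% and 27.8 to 68.7%, include the genome-wide 65.5%. A hairpin acts on the transcript, so peaks at the HMGA1 locus do not check the labels. The band of JAK2, 9p24.1, held 1889 control and 1781 shHMGA1 peaks, a ratio of 0.943.

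Bands of other blood cell genes, from the same 17, varied around the whole-list ratio of 0.886. The band of the haematopoietic regulator RUNX1, 21q22.12, held 167 and 166 peaks, and that of MYB, 6q23.3, 197 and 196. The band of MYC, 8q24.21, held 109 control and 84 shHMGA1 peaks (0.771), with 31 control-only against 4 shHMGA1-only peaks (88.6% control-only, exact interval 73.3 to 96.8). The band of the stem cell factor receptor KIT, 4q12, held 163 and 135 peaks (0.828), and that of the β-globin gene HBB, 11p15.4, held 312 and 269 (0.862). The band of the platelet integrin gene ITGA2B, 17q21.31, held 163 and 154 peaks (0.945). The remaining bands held 152 control and 126 shHMGA1 peaks for ERG, 78 and 73 for GATA1, 231 and 206 for TAL1, 152 and 142 for PF4, 253 and 258 for KLF1, and 786 and 723 for CDKN2A. Such counts cover whole bands and are not values of these genes. All peaks of 9p21.3, the band of CDKN2A, lay outside its 3.77 Mb without a peak. Where the gene lies in that band was not annotated here.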

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

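The alternatives that filtered 1 list only or left out the dense segments, and all those on the ratio of peak numbers, on blocks, on the density of the 4q and 9p segments and on the control-only share, were chosen after seeing the data. The shHMGA1 list stayed the shorter under each alternative that changed the lists, except equal numbers, which remove that difference by construction. The overlap rules left the lists unchanged. Control peaks were the less often overlapped under each alternative. A longer list is overlapped less often in part by its length, and with equal numbers the gap was small. The stricter threshold (joined median summit −log10 p of 5.24) left 64011 control and 55895 shHMGA1 peaks (ratio 0.873), with 78.2% and 89.7% overlapped and 13925 control-only and 5773 shHMGA1-only peaks. With 56305 peaks from each list, 84.5% of control and 85.1% of shHMGA1 peaks were overlapped, and 8706 control-only and 8417 shHMGA1-only peaks were left. Reciprocal overlap of 50% gave 62.3% and 70.4%, with 47878 and 33335 unshared peaks. A distance of 500 bp gave 78.8% and 87.6%. Filtering only the counted list gave 96.0% and 98.5%, with 2567 and 833 unshared peaks. Without the dense segments the ratio was 0.877 and the overlaps 74.1% and 84.7%. Chromosomes 1 to 22 and X alone, and merged peaks, moved none of these whole-list ratios and overlaps beyond their counting intervals, or the counts by over 1.5 times. Densities of the segments did move. Merging lowered the control density to 9.55 times the rest on 4q and 9.55 on 9p, and the stricter threshold to 5.85 and 10.1. In the shHMGA1 list the values were 10.1 and 10.4 with merging, and 5.11 and 9.57 under the stricter threshold. Under the stricter threshold, equal numbers and merging, the ratio of the 11q block was 0.661 to 0.874 and that of the 1p block 1.01 to 1.20. The whole-list ratio was 0.873 under the stricter threshold and 0.890 under merging, and equal numbers fix it by construction. Intervals of these ratios treat the lists as independent counts, although most sites are shared, so the unshared peaks were also counted. The control-only share was 77.6 to 88.4% in the 11q block and 24.6 to 44.4% in the 1p block, against 50.8 to 70.7% for the whole lists; the blocks were chosen for this pattern, so it is no independent check. Under the stricter threshold the intervals of the 1p block (35.3 to 53.9%) and the 5q block (19.9 to 56.1%) included equal numbers. No paired analysis was possible because each group has 1 list without values per sample or replicate numbers, and for the same reason no replicate could be left out. The planned promoter, gene list and motif alternatives were not run. Unknown read depth limits every count of weak peaks.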

Other observations

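All the tests weighed here except the one on neighbouring bands were chosen after the result was seen. That one was set before its own result, but after the regional pattern was known. A simpler form, without the adjustment and without leaving out bands, had by then given a Spearman rho of 0.49 over 610 bands. Over the 573 bands kept for the adjusted test, the unadjusted rho was 0.45.

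The most significant peaks were spread over the genome differently from the lists as a whole. Outside the dense segments, control peaks numbered 40.1 per Mb in Giemsa-negative bands, which are rich in genes, and 37.3 per Mb in the darkest Giemsa-positive bands. In the most significant decile the numbers were 5.13 and 2.57 per Mb, and in the shHMGA1 list 4.54 and 2.33. Chromosome 19, which is rich in genes, held 35.0 control peaks per Mb, fewer than chromosome 13 with 39.2, but in the most significant decile it held 6.97 per Mb against 3.13.

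The single most significant peak of both lists was on chromosome 1 at 1p36.33, from 564398 to 570361 in control, a stretch known to copy part of the mitochondrial genome. All of the 10 most significant control peaks were shared, and 9 of them overlapped one of the 10 most significant shHMGA1 peaks. Among them were a peak in the centromeric band 19q11 and one in the variable band 21p11.2. Regions prone to mapping errors were not removed here, so the sharing of these top peaks is no check on open chromatin. At the 41 chromosome ends with at least 100 control peaks in the last 10 Mb, the shHMGA1 list held 17261 peaks and the control list 20587, a ratio of 0.838 against 0.895 elsewhere, and 25 of the 41 ends were below the whole-list ratio.

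The first pattern is the shorter shHMGA1 list. A complete loss of the strongest control sites is argued against, since 0% of the most significant decile of control peaks lacked an overlapping shHMGA1 peak. A partial loss of signal at these sites was not tested. A much weaker peak would still count as shared, and peak heights were not compared between lists. Fewer weak peaks passing the calling threshold was not decided: 92.1% of control-only peaks lay below the median significance of the control list, but so did 94.8% of shHMGA1-only peaks in theirs. Lower read depth or library quality and a broad weakening of accessibility after HMGA1 silencing stay open because the lists hold no read counts.

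The second pattern is the regional unevenness, with fewer shHMGA1 peaks on distal 11q and, among all peaks, more on 1p34. The ratio of the 1p block was 1.01 under the stricter threshold and 1.12 (interval 0.984 to 1.27) with equal numbers of the most significant peaks. One lower calling power over the whole genome is argued against only as far as it acts through summit significance. Peak area and width, through which it may also act, were not adjusted for, so it stays open in that form. After subtraction of the control-only share that the significance of each band's own peaks gives, and without the blocks, extreme bands and dense segments, 420 neighbouring pairs of bands correlated with a Spearman rho of 0.47, while the highest of 10000 shuffles reached 0.179. A different DNA copy number of such blocks in the cultures and a regional chromatin change under HMGA1 silencing cannot be told apart: both may make paired peaks narrower, as on 11q24.1 to 11q25 (median log2 width ratio -0.15), and each group has 1 list and no genomic DNA control analysed here. A library bias that follows base composition was not tested and stays open.

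The third pattern is the dense calling on 4q and 9p. On 4q, the excess over the rest was 19.1 times in the weakest decile of control peaks and 3.49 times in the most significant. Open chromatin that raises strong and weak peaks alike is argued against as the whole cause. Extra DNA copies in this line lifting weak signal over the threshold, and chromatin opened broadly but weakly, cannot be told apart by that profile. On 9p the profile also decides nothing, and the lists differ. In control the excess was 13.25 times in the weakest decile, highest in the sixth at 15.43, still 11.15 in the eighth and 5.03 in the most significant. In the shHMGA1 list it was highest in the weakest decile (18.9, interval 17.6 to 20.1) and 4.70 in the most significant. The 3.77 Mb of 9p21.3 without a peak, flanked by 374 and 463 control peaks per Mb, could be a deletion, which was not tested. No copy number data were analysed here, and more accessible chromatin stays open as an explanation in both segments.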
